A study of Escherichia coli K-12 with 30 samples.

How the data were processed

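RNA was sequenced from 30 cultures of Escherichia coli K-12 MG1655 grown in Kornberg medium, a rich phosphate-buffered medium with yeast extract and glucose, to stationary phase, at an optical density of 2.0. Ribosomal RNA was depleted and strand-specific libraries were made. Every strain carried a pgaC genotype, pgaC being the gene for the glycosyltransferase that makes the biofilm polysaccharide poly-N-acetylglucosamine (PGA). The 10 groups had 3 biological replicates (A, B and C) each. The parent, here called wild type, and strains labelled csrA, csrB csrC, csrD, csrA csrD, and csrB csrC csrD carried the empty vector pBR322. The other 4 strains had a plasmid copy: the csrA csrD strain with csrA or with csrD, and the csrB csrC csrD strain with csrB or with csrD. The sample titles name the mutated genes and not the alleles. Loss of a gene, or a strain without it, refers here to that label. Groups and replicate letters were taken from the sample labels, which describe the replicates as biological.

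The table deposited by the authors holds raw counts, whole numbers of reads per gene for 4497 genes, without normalization and with a column for each library. The submitters' processing notes name CASAVA, Bowtie and HTSeq. Their versions and settings, the genome build, the annotation and the strand setting of the counting step are not given in the sources used here. A gene's count can therefore hold reads from a transcript that overlaps it or runs into it from a neighbour, on either strand. Gene names and the order of neighbouring genes came from a RefSeq gene table of assembly ASM584v2, to which 4487 of the 4497 identifiers matched and 10 did not. No coordinates are given. Library totals ran from 12006001 to 21144663 counts. For a gene with 0 counts the limit was set at 3 counts over the group. Such limits cover counting error only, as reads without molecular identifiers are not independent molecules.

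Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes passing filterByExpr were kept, which left 4216 genes tested and 281 not tested, libraries were scaled by TMM, and a robust quasi-likelihood model with a mean per group was fitted to all 30 libraries together. Contrasts were tested with the quasi-likelihood F test and p-values were adjusted by Benjamini and Hochberg over all genes tested. Genes with an adjusted p under 0.05 are called here. Standard errors of log2 fold changes were taken as the absolute log2 fold change divided by the square root of F. Levels are CPM, library-scaled counts from the cpm function of edgeR with TMM factors, as mean ± SD of 3 libraries. The csrA, csrB csrC and csrD strains were each tested against wild type. The csrA csrD and csrB csrC csrD strains were each tested against the strain that differed by csrD only. Each plasmid strain was tested against its empty-vector strain. In addition, 2 interactions were tested, the effect of losing csrD in the csrA or the csrB csrC background minus that in wild type.

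Before the data were examined, 29 gene lists were fixed from general knowledge: glycogen metabolism, glycolysis, gluconeogenesis, TCA cycle, glyoxylate shunt and acetate uptake, PGA polysaccharide (without pgaC), curli, flagellum class 1 and 2, flagellum class 3 and chemotaxis, c-di-GMP enzymes, RpoS general stress response, acid resistance, ribosomal proteins, Fur iron acquisition, heat shock, SigmaE envelope stress, histidine, arginine and purine biosynthesis, sulfur assimilation, maltose system, glycerol and glycerol 3-phosphate use, hydrogenases and acid-induced oxidases, colanic acid, peptide and starvation carriers, tryptophanase, Csr circuit, direct CsrA targets from textbooks, and ribosomal RNA. Some lists share members; dgcT, for example, is in the PGA, c-di-GMP and direct target lists. Each list was tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over lists within a contrast, and again with a correlation estimated from the data. The number of members called was counted over all genes tested and adjusted over the list alone. The median, the mean and the camera direction of a list differed in sign in 36 of the 319 list tests, of which 1 was called.

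Named genes were set by a rule made before the data were examined. It took csrA, csrB, csrC, csrD and pgaC first, then the 10 largest changes in each direction in the contrasts of mutants with wild type and of plasmid csrA, and 5 in the others, among called genes whose libraries did not overlap between groups and that reached 10 CPM in the higher group, and up to 4 members of each list by p-value. Agreement of contrasts was measured as Pearson's r across 4208 genes, leaving out csrA to csrD and pgaA to pgaD, for 36 pairs of contrasts. Genes are not independent replicates, so no p is given. Where contrasts shared libraries, the covariance was set beside that of 20 simulated draws without group differences. Alternatives were DESeq2 1.42.0, RLE or upper-quartile scaling, no low-count filter, the replicate letter as a block, the libraries of the contrast alone, leaving out 178 non-coding and engineered genes, and leaving out each library in turn. Leaving out the 4 genes on each side of csrB and csrC was added after seeing the data. The pipeline was tested on simulated data with 200 changed genes per contrast. For csrA against wild type it recovered 63.3% of genes changed 2-fold and 98% of those changed 4-fold, and for the interactions 40% and 38% of genes changed 2-fold. No pair of libraries of a group agreed within counting noise: the lowest chi-square per gene between replicates was 8.85.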

Results

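CsrA is an RNA-binding protein that blocks or promotes translation and turnover of many messenger RNAs. CsrB and CsrC are small RNAs that bind and sequester CsrA, and CsrD is a membrane protein known to promote turnover of CsrB and CsrC by RNase E. The design asked for the order of action of these regulators by comparing transcriptomes of single, double and triple mutants and of strains with plasmid copies. Each of the 10 strains was represented by 3 cultures. Libraries held between 12006001 counts (csrA csrD strain, replicate A) and 21144663 (csrB csrC csrD strain with plasmid csrD, replicate A). The first principal component of log2 CPM took 60.8% of the variance and the second 10.1%. Wild-type replicate C stood apart from replicates A and B, at -6.16 on the first component against -24.6 and -24.7.

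Transcript levels at the targeted genes followed the genotypes for csrB and csrD. csrD stood at 58.9 ± 7.62 CPM (SD, n = 3) in wild type and at 0.976 ± 0.438 CPM in the csrD strain, and csrB at 8640 ± 1222 CPM in wild type and 4.47 ± 1.38 CPM without csrB and csrC. csrC fell from 3373 ± 375 to 84.7 ± 4.59 CPM in that strain, and csrA from 361 ± 8.78 to 232 ± 9.54 CPM in the csrA strain, so some reads over these loci remained in the mutants. Whether some CsrA function remained in the csrA strain can not be told from these reads. pgaC, altered in every strain, still had reads, at 3.38 ± 0.568 CPM in wild type, 113 ± 13.1 CPM without csrA and 270 ± 23.2 CPM with plasmid csrB. Plasmid csrA brought csrA to 1873 ± 171 CPM, plasmid csrB brought csrB to 22969 ± 1597 CPM, and plasmid csrD brought csrD to 1095 ± 88.0 CPM in the csrA csrD strain and 672 ± 46.8 CPM in the csrB csrC csrD strain.

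**Figure D1:**
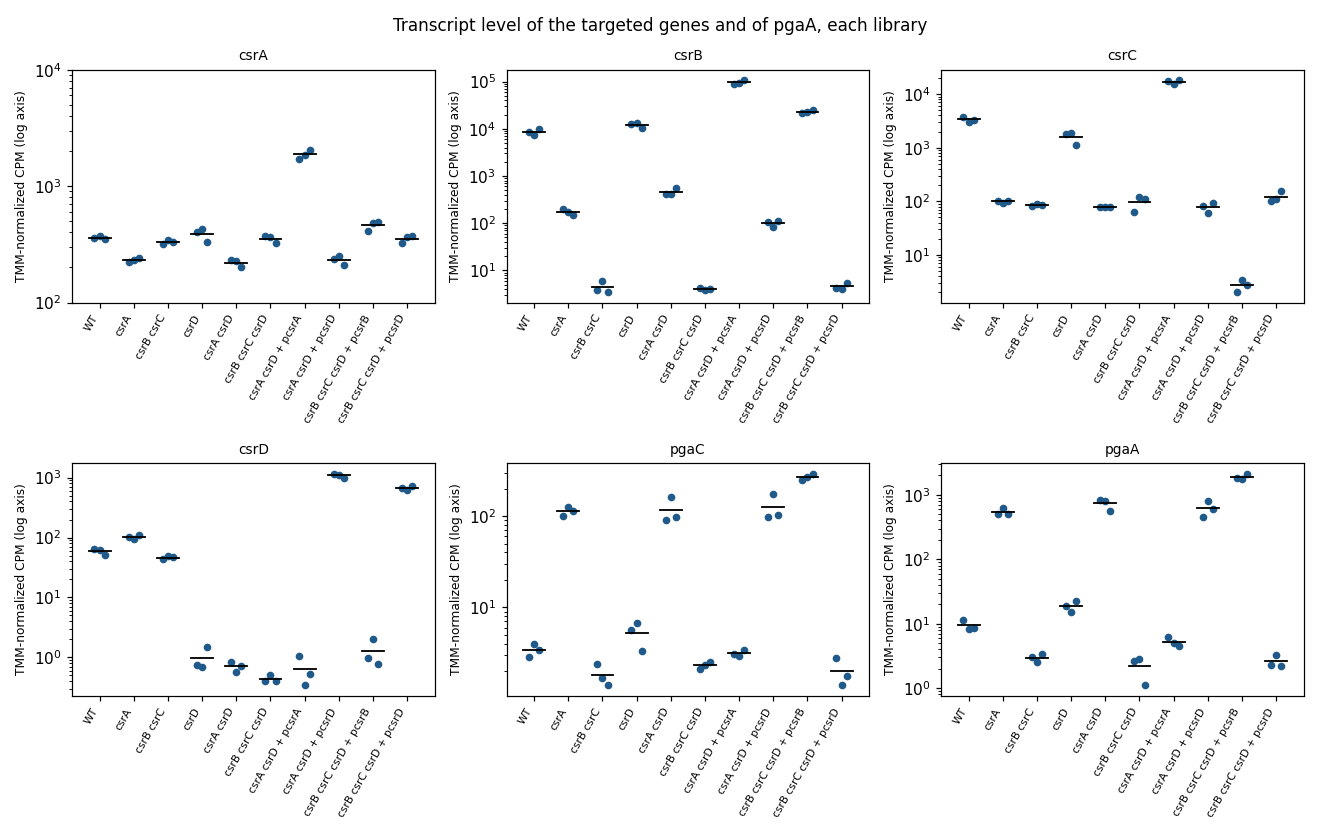
TMM-normalized CPM (log axis) of csrA, csrB, csrC, csrD, pgaC and pgaA in the 10 strains; each point is a library and each bar the mean of 3. csrB ran from 4.04 CPM in the csrB csrC csrD strain to 96072 CPM in the csrA csrD strain with plasmid csrA.

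The first comparison asked what CsrA controls. Loss of csrA raised the PGA genes pgaA, pgaB and pgaC, raised carbon storage genes and lowered the small RNAs that bind CsrA. The change of pgaD did not pass the test (1.63 ± 0.567 and 1.84 ± 0.328 CPM, SD, n = 3, edgeR adjusted p = 0.59). Even with plasmid csrB, where pgaA reached 1909 ± 208 CPM, pgaD stood at 2.79 ± 0.614 CPM. That was a rise called by edgeR, from 1.61 ± 0.0702 CPM in the empty-vector csrB csrC csrD strain. As pgaD lies beside pgaC, which was altered in every strain, whether CsrA controls pgaD can not be told here. pgaA (b1024), which encodes the outer membrane PGA porin, rose 57.1-fold (log2 5.84, SE 0.29, edgeR adjusted p = 2.16e-13), from 9.49 ± 1.73 to 542 ± 72.6 CPM (SD, n = 3), and pgaB, the PGA deacetylase, rose 68.9-fold. The diguanylate cyclase genes dgcT and dgcZ rose 19.6-fold and 10.8-fold, the ferritin-like gene ftnB 32.4-fold, and acs, acetyl-CoA synthetase, 17.3-fold. csrB (b4408) fell 50.5-fold to 171 ± 24.0 CPM (edgeR adjusted p = 1.06e-15), csrC fell 33.9-fold, and uvrY, the response regulator that drives their transcription, fell 2.35-fold. Apart from csrB and csrC, the largest falls by the rule for named genes were in yghW (212-fold), yhjX (92.2-fold), the fumarate respiration genes dcuB (37.8-fold) and fumB (30.9-fold), the porin gene ompW (32.1-fold) and modA, the molybdate-binding protein gene (26.4-fold). Of 4216 genes tested, edgeR called 1995, of which 1033 were higher and 962 lower, and 908 differed at least 2-fold. Which direction held more genes depended on the setting, with 988 higher and 1049 lower by RLE scaling, 1011 and 1090 by DESeq2, 991 and 993 without non-coding and engineered genes, and 981 and 1031 without csrA replicate B.

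Central metabolism moved as groups in the csrA strain. All 6 glycogen genes rose (6 adjusted over the list alone, median log2 2.22, camera adjusted p = 2.94e-06), among them glgC, the ADP-glucose pyrophosphorylase gene, at 7.70-fold, from 248 ± 70.9 to 1906 ± 140 CPM. All 15 TCA cycle genes rose (15 adjusted over the list alone, median 2.65), with acnA at 11.5-fold and sucD at 9.04-fold. For this list camera gave an adjusted p = 3.09e-07, and adjusted p = 0.29 with an estimated correlation. The 6 genes of the glyoxylate shunt and acetate uptake rose (6 adjusted over the list alone, median 2.34, camera adjusted p = 0.000176, and adjusted p = 0.264 with an estimated correlation). Of 11 glycolysis genes 10 fell and 1 rose, with the same numbers adjusted over the list alone (median -1.11, camera adjusted p = 0.000146, and adjusted p = 0.29 with an estimated correlation). pykA, pyruvate kinase, fell 4.35-fold and eno, enolase, 2.62-fold. All 14 purine biosynthesis genes fell (14 adjusted over the list alone, median -3.53, camera adjusted p = 2.04e-15), purC from 1055 ± 132 to 80.8 ± 6.54 CPM and purH 14-fold. Ribosomal protein genes fell in 50 of 54 cases (53 adjusted over the list alone, median -0.62, camera adjusted p = 1.84e-12, and adjusted p = 0.38 with an estimated correlation).

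Stress and motility genes of the csrA strain divided. All 31 genes of the RpoS general stress list rose (31 adjusted over the list alone, median log2 2.26, camera adjusted p = 2.9e-20, and adjusted p = 0.076 with an estimated correlation), including osmC at 12.7-fold and katE, catalase HPII, at 7.88-fold. Of the 31 flagellar class 1 and 2 genes 25 fell (30 adjusted over the list alone, median -0.94, camera adjusted p = 8.13e-06, and adjusted p = 0.629 with an estimated correlation), with flhD and flhC, the flagellar master regulator, 2.65-fold and 2.49-fold lower. The PGA list had 4 of 5 genes higher (4 adjusted over the list alone, median 4.29, camera adjusted p = 9.35e-06). The direct CsrA targets had 8 of 14 genes higher and 3 lower, with the same numbers over the list alone (camera adjusted p = 0.00142). The c-di-GMP enzymes had 11 of 25 genes higher and 5 lower (13 and 7 adjusted over the list alone, camera adjusted p = 0.0238, and adjusted p = 0.29 with an estimated correlation). The Csr circuit list had 7 of 12 genes lower and 1 higher, with the same numbers over the list alone (camera adjusted p = 0.000411). As this list holds csrA, csrB, csrC and csrD, its test in each contrast includes genes altered or supplied in these strains. The direct CsrA target list also holds csrA, and it shares pgaA, dgcT and nhaR with the PGA list. Its call is therefore not separate from that of the PGA list. Fur iron acquisition genes rose in 6 of 30 cases (0 adjusted over the list alone, median 0.91, camera adjusted p = 0.0119, and adjusted p = 0.85 with an estimated correlation). This list averaged 4.27 log2 CPM in wild-type replicate C against 1.71 and 1.66 in replicates A and B. Hydrogenase and acid-induced oxidase genes fell in 8 of 10 cases (9 adjusted over the list alone, median -2.03, camera adjusted p = 0.0238, and adjusted p = 0.825 with an estimated correlation). This list averaged 6.12 log2 CPM in wild-type replicate A against 3.99 and 3.56 in the others. Without replicate A hyaA, hyaB, hyaC and hyaE, at log2 -1.38, -1.28, -0.91 and -0.70, were no longer called.

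For the other 15 lists the camera adjusted p ran from 0.0521 to 0.888 in the csrA strain. Gluconeogenesis genes rose in 5 of 6 cases and fell in 1, and acid resistance genes rose in 3 of 14. Peptide and starvation carriers fell in 6 of 12 and rose in 1. Heat shock genes rose in 5 of 16 and fell in 1, and arginine biosynthesis genes rose in 3 of 12 and fell in 1. Flagellar class 3 and chemotaxis had 2 genes higher and 1 lower, SigmaE envelope stress 3 higher, glycerol use 1 higher and 3 lower, curli 2 lower, histidine biosynthesis 1 lower and ribosomal RNA 1 lower. Sulfur assimilation, maltose, colanic acid and tryptophanase had 0 genes called by edgeR in a strain where 2285 genes had an unadjusted p under 0.05 and DESeq2 called 2101. The camera calls for glycogen, PGA, purine biosynthesis, the Csr circuit and the direct CsrA targets held with an estimated correlation, at adjusted p = 0.0415, 0.00992, 0.0271, 0.00992 and 0.0219.

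**Figure D2:**
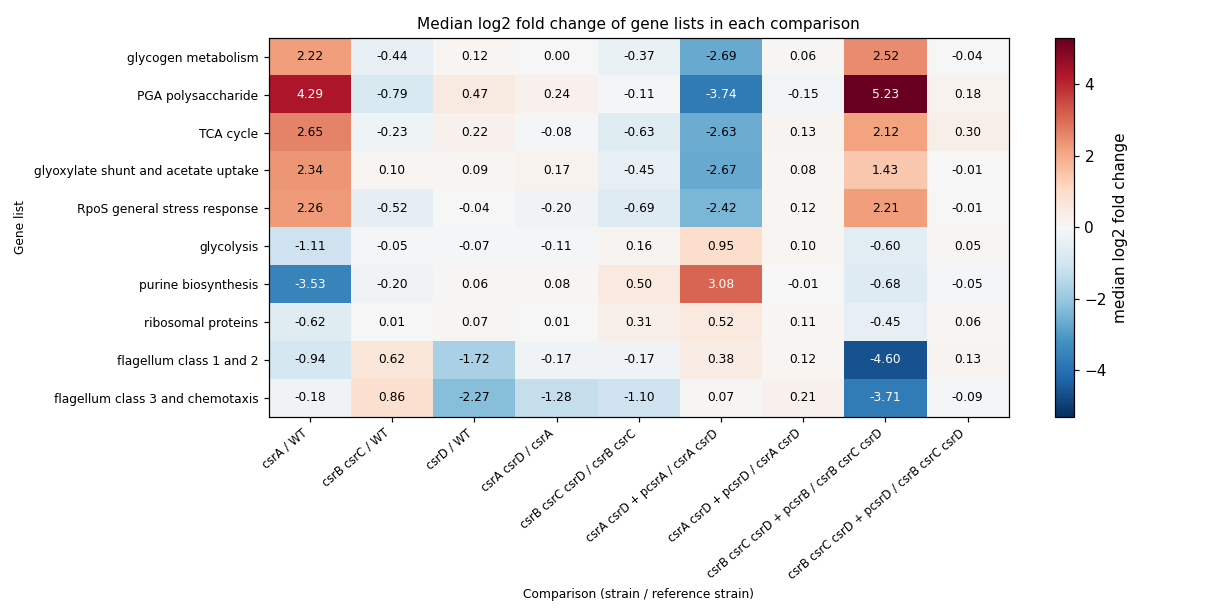
Median log2 fold change (colour scale and printed value) of 10 gene lists in the 9 pairwise comparisons of strains. The TCA cycle median was 2.65 in the csrA strain, -2.63 with plasmid csrA and 2.12 with plasmid csrB.

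Loss of csrB and csrC, which leaves CsrA without these small RNA antagonists, changed far fewer genes. PGA genes fell: pgaB 4.56-fold (log2 -2.19, SE 0.30, edgeR adjusted p = 6.4e-05) and pgaA 3.18-fold, from 9.49 ± 1.73 to 2.99 ± 0.396 CPM (SD, n = 3), and dgcZ fell 2.14-fold. The largest rises were beside the altered loci. yihI, next to csrC, rose 69.7-fold to 6993 ± 568 CPM and hemN rose 9.16-fold. Next to csrB, yqcC, truC and yqcA rose 59.8-fold, 27.4-fold and 7.57-fold. As the strand setting is not given, read-through from the altered loci cannot be separated from these genes' own transcripts. Away from these loci the osmoporin gene ompF rose 2.40-fold (edgeR adjusted p = 0.00277) and rdcA 2.37-fold, and ygiW fell 2.49-fold. The prophage gene ybcM had 0 counts against 546 in wild type, at least 196-fold lower. The acid resistance genes gadC, for a glutamate antiporter, and gadB, for a glutamate decarboxylase, fell 4.82-fold and 4.51-fold, a call lost without wild-type replicate A (log2 -1.60 and -1.55) and without any replicate of the csrB csrC strain.

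In the csrB csrC strain edgeR called 107 genes, 40 higher and 67 lower, 40 of them at least 2-fold. Leaving out replicate B or replicate C of the csrB csrC strain each left 49 calls, DESeq2 called 208, and the fit to the libraries of these 2 strains alone called 31, of which 18 were higher and 13 lower. The PGA list had 3 of 5 genes lower (4 adjusted over the list alone, median log2 -0.79, camera adjusted p = 6.5e-05, and adjusted p = 0.0305 with an estimated correlation), the only 1 of 12 list calls that held. RpoS list genes fell in 4 of 31 cases (14 adjusted over the list alone, median -0.52, camera adjusted p = 6.58e-10, and adjusted p = 0.329 with an estimated correlation), with elaB 1.59-fold and msyB 2.38-fold lower. The calls of its members katE and cbpA were lost without csrB csrC replicate B (log2 -0.93 and -0.72) or C (-0.89 and -0.70), among other libraries. Acid resistance genes fell in 2 of 14 cases (11 adjusted over the list alone, median -1.36, camera adjusted p = 5.44e-08, and adjusted p = 0.329 with an estimated correlation). This list averaged 7.63 log2 CPM in wild-type replicate A, 6.59 and 6.38 in replicates B and C, and 5.47 to 5.83 without csrB and csrC. For flagellar class 3 and chemotaxis the median was 0.86, and 1 of 21 genes, trg, was called higher (9 adjusted over the list alone). For this list camera gave an adjusted p = 4.05e-09, and adjusted p = 0.372 with an estimated correlation. The trg call was lost without any library of these strains but csrB csrC replicate A (log2 0.71 to 0.78). The Csr circuit list had a median of 0.05 and a mean of -1.29, opposite in sign, since 2 of its 12 members, csrB and csrC, fell (1 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.0267, and adjusted p = 0.166 with an estimated correlation).

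Genes for motility were lower in the csrD strain than in wild type. All 21 flagellar class 3 and chemotaxis genes fell (21 adjusted over the list alone, median log2 -2.27, camera adjusted p = 5.63e-66), among them the stator genes motA and motB at 5.94-fold and 6.04-fold and tsr, the serine chemoreceptor, from 521 ± 75.1 to 93.8 ± 36.6 CPM (SD, n = 3). Of 31 flagellar class 1 and 2 genes 29 fell (29 adjusted over the list alone, median -1.72, camera adjusted p = 3.67e-69). Plasmid csrD was not supplied in this background. In the mutant backgrounds it gave back little or none of the class 3 fall, as described below. pdeH, the main c-di-GMP phosphodiesterase and itself part of the flagellar regulon, fell 6.17-fold (log2 -2.63, SE 0.44, edgeR adjusted p = 0.000715), and uhpT, the hexose phosphate carrier, 5.78-fold. Few genes rose: osmB 2.14-fold (log2 1.10, SE 0.23, edgeR adjusted p = 0.00504), yieF 1.52-fold, and ftnB 2.28-fold, the last no longer called without wild-type replicate C (log2 0.999). pgaA was 1.98-fold higher, a call lost without wild-type replicate B or C or without csrD replicate A or C (log2 0.88 to 0.99).

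Without csrD, csrC fell and the change of csrB did not pass the test. csrB stood at 12206 ± 1637 CPM against 8640 ± 1222 CPM in wild type (SD, n = 3; log2 0.50, SE 0.17, edgeR adjusted p = 0.226). csrC fell 2.09-fold, from 3373 ± 375 to 1611 ± 426 CPM (log2 -1.07, SE 0.22, edgeR adjusted p = 0.00495), a call lost without csrD replicate C (log2 -0.83). edgeR called 97 genes, 17 higher and 80 lower, with 78 at least 2-fold, and the fit to the libraries of these 2 strains alone called 27, of which 1 was higher and 26 lower. The number called higher was 8 without wild-type replicate C, 10 without its replicate B and 32 by DESeq2. Both flagellar list calls held with an estimated correlation (adjusted p = 0.00674 and 0.00613 for class 1 and 2 and for class 3, camera), and 2 of the 15 list calls did so. The PGA list had 1 of 5 genes higher (3 adjusted over the list alone, median 0.47, camera adjusted p = 0.00289, and adjusted p = 0.0606 with an estimated correlation). The curli list had 1 of 7 genes lower (3 adjusted over the list alone, median -0.67, camera adjusted p = 2.67e-05, and adjusted p = 0.0606 with an estimated correlation).

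**Figure D3:**
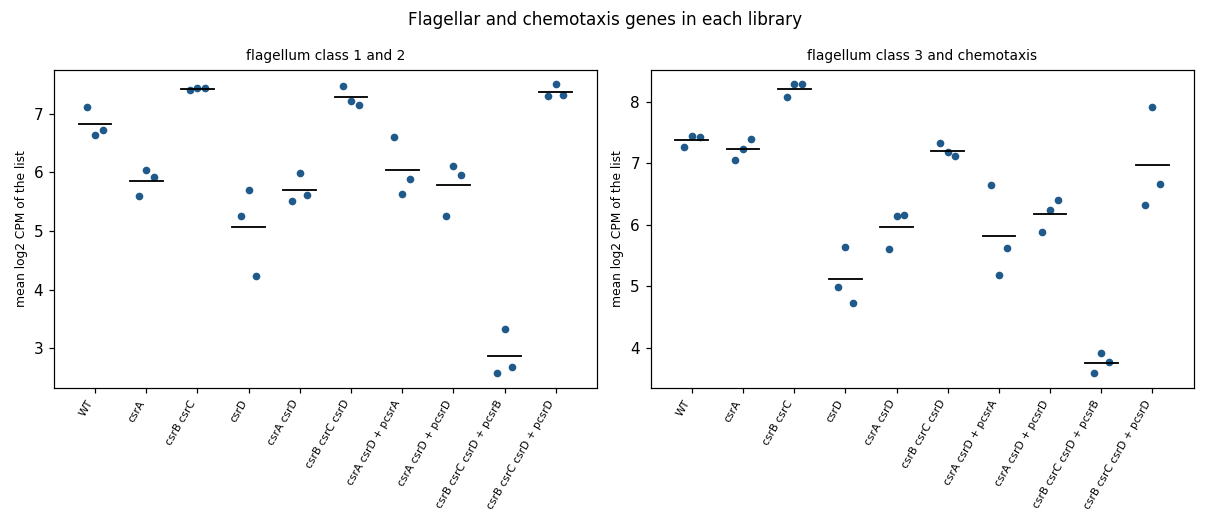
Mean log2 CPM over the genes of the 2 flagellar lists in the 10 strains; each point is a library and each bar the mean of 3. Class 3 and chemotaxis genes stood between 7.26 and 7.44 in wild type, between 4.73 and 5.63 in the csrD strain and between 3.59 and 3.92 with plasmid csrB.

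Without csrA, the genes called by edgeR after removing csrD were csrD itself and csrB. csrB rose 2.72-fold, from 171 ± 24.0 to 466 ± 83.4 CPM (SD, n = 3; log2 1.44, SE 0.17, edgeR adjusted p = 4.68e-05), and csrC stood at 78.8 ± 1.36 against 99.6 ± 4.56 CPM (log2 -0.34, edgeR adjusted p = 0.576). Flagellar class 3 and chemotaxis genes had a median of -1.28, with 0 of 21 called over all genes and 21 lower adjusted over the list alone (camera adjusted p = 1.34e-27, and adjusted p = 0.264 with an estimated correlation). The flagellar class 1 and 2 median was -0.17. edgeR called 2 genes, with 434 at an unadjusted p under 0.05. DESeq2 called 20, the fit to the libraries of these 2 strains alone 12, and edgeR 16 without csrA replicate B and 5 without csrA csrD replicate C. None of 6 camera list calls held with an estimated correlation.

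Without csrB and csrC, the genes of type 1 fimbriae, the surface adhesins encoded by the fim operon, were lower in the strain that also lacked csrD. fimI fell 2.89-fold (log2 -1.53, SE 0.19, edgeR adjusted p = 5.92e-05), from 114 ± 22.7 to 39.6 ± 2.86 CPM (SD, n = 3), and fimC 2.73-fold. The 7 fim genes also fell in the csrD strain and in the csrA strain against wild type (median log2 -1.16 and -1.12, 7 of 7 called in each). Plasmid csrD in the csrB csrC csrD strain gave back 21.6% of their median fall in that background, with 0 of 7 called by edgeR. The cause of the fall therefore stays open. The osmoprotectant transport genes proX and proW fell 2.99-fold and 2.87-fold, and degP, the periplasmic protease, rose 1.73-fold; the degP call was lost without any single library of these 2 strains (log2 0.73 to 0.83), and the proX and proW calls without any but csrB csrC replicate A (log2 -1.37 to -1.71 and -1.39 to -1.67). edgeR called 18 genes, 2 higher and 16 lower, with 571 at an unadjusted p under 0.05, and DESeq2 called 80, of which 27 were higher and 53 lower. The edgeR count was 8 without csrB csrC replicate B, 9 without its replicate C, and 7, 9 and 11 without replicates A, B and C of the csrB csrC csrD strain. The fit to the libraries of these 2 strains alone called 45. RpoS list genes fell in 3 of 31 cases (23 adjusted over the list alone, median -0.69, camera adjusted p = 1.29e-18, and adjusted p = 0.303 with an estimated correlation). Flagellar class 3 and chemotaxis had a median of -1.10, 0 of 21 called and 16 lower adjusted over the list alone (camera adjusted p = 8.03e-15, and adjusted p = 0.303 with an estimated correlation), and 0 of 9 list calls held with an estimated correlation.

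Whether loss of csrD acted differently in the mutant backgrounds was tested as an interaction. No gene passed by edgeR in the csrA or in the csrB csrC background (0 called in each; smallest edgeR adjusted p = 0.131 and 0.243), with 399 and 298 genes at an unadjusted p under 0.05. DESeq2 called 17 and 6, and edgeR 1 in the csrA background without wild-type replicate B. Flagellar class 1 and 2 genes had interaction medians of 1.53 and 1.5, with 0 of 31 called and 29 adjusted over the list alone in each background (camera adjusted p = 5.96e-35 and 6.55e-44, and adjusted p = 0.237 and 0.0875 with an estimated correlation). The 79 genes that fell without csrD in the wild-type background, other than csrD, had a median log2 fold change of -1.76 there. Their median was -0.34 in the csrA background, where 69 of 79 were lower and 0 called, and -0.43 in the csrB csrC background, where 73 of 79 were lower and 7 called. The 17 genes that rose had medians of 0.75, -0.04 and -0.05 in the 3 backgrounds. These genes were chosen on the wild-type contrast, which alone favours larger values there.

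Plasmid csrA moved the PGA, storage and purine genes opposite to loss of csrA, but few flagellar genes. In the csrA csrD strain it lowered pgaB 195-fold and pgaA 142-fold, from 737 ± 150 to 5.20 ± 0.855 CPM (SD, n = 3; log2 -7.14, SE 0.31, edgeR adjusted p = 8.91e-15), and ftnB 30.9-fold. It raised yghW 171-fold, yhjX 158-fold, modA 33.4-fold and purT, a formate-dependent purine enzyme, 20.7-fold. csrB rose 206-fold to 96072 ± 9095 CPM and made up 8.08 to 9.88% of all counts in these libraries, and csrC rose 217-fold to 17134 ± 1422 CPM (edgeR adjusted p = 1.68e-17 and 6.86e-16). All 14 purine genes rose (14 adjusted over the list alone, median 3.08, camera adjusted p = 2.3e-15). All 6 glycogen genes fell (6 adjusted over the list alone, median -2.69, camera adjusted p = 2.54e-07), and 4 of 5 PGA genes fell (4 adjusted over the list alone, camera adjusted p = 1.3e-06). These 3 calls and that of the Csr circuit (6 of 12 genes higher, 6 adjusted over the list alone, camera adjusted p = 1.53e-05) held with an estimated correlation, at adjusted p = 0.0281, 0.0281, 0.00328 and 0.0028.

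In the same strain all 31 RpoS list genes fell (31 adjusted over the list alone, median -2.42, camera adjusted p = 2.34e-22, and adjusted p = 0.0565 with an estimated correlation). All 15 TCA cycle genes fell (15 adjusted over the list alone, median -2.63, camera adjusted p = 2.25e-07, and adjusted p = 0.273 with an estimated correlation), and 47 of 54 ribosomal protein genes rose (48 adjusted over the list alone, median 0.52, camera adjusted p = 1.04e-11, and adjusted p = 0.412 with an estimated correlation). Fur iron acquisition genes fell in 25 of 30 cases (26 adjusted over the list alone, median -2.76, camera adjusted p = 1.87e-06, and adjusted p = 0.555 with an estimated correlation), entE, an enterobactin synthesis gene, by 45.4-fold from 56.9 ± 50.4 to 1.24 ± 0.703 CPM. Of the flagellar class 1 and 2 genes, 25 of which fell without csrA, 2 of 31 rose with plasmid csrA (0 adjusted over the list alone, median 0.38, camera adjusted p = 0.0648). Of class 3 and chemotaxis genes 1 of 21 fell (1 adjusted over the list alone, camera adjusted p = 0.814), with a median of 0.07 and a mean of -0.03 that differed in sign. The strain with plasmid csrA still lacked csrD, and both flagellar lists were also lower in the csrD strain (medians -1.72 and -2.27). Whether plasmid csrA would restore these genes with csrD present can therefore not be told. Maltose genes fell in 8 of 11 cases (8 adjusted over the list alone, median -2.19, camera adjusted p = 0.0459, and adjusted p = 0.727 with an estimated correlation). edgeR called 1803 genes, 813 higher and 990 lower, and 883 at least 2-fold. With upper-quartile scaling 907 were higher and 893 lower.

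Plasmid csrB in the csrB csrC csrD strain moved genes in the direction seen without csrA and lowered the flagellar regulon. pgaA rose 860-fold, from 2.19 ± 0.938 to 1909 ± 208 CPM (SD, n = 3; log2 9.75, SE 0.35, edgeR adjusted p = 2.38e-16), pgaB 898-fold, ftnB 73.9-fold and dgcT 37.5-fold. All 31 flagellar class 1 and 2 genes fell (31 adjusted over the list alone, median -4.60, camera adjusted p = 1.44e-34, and adjusted p = 0.0616 with an estimated correlation), with flgB 38.9-fold and flgE 33.5-fold lower. In addition, 20 of 21 class 3 and chemotaxis genes fell (21 adjusted over the list alone, median -3.71, camera adjusted p = 3.99e-19, and adjusted p = 0.137 with an estimated correlation). yihI, beside csrC, fell 38.9-fold and csrC 35.8-fold, to 2.75 ± 0.692 CPM. As csrC was already altered in the empty-vector strain (98.8 CPM), the csrC sites of these strains may differ, which remains open. Changes assigned to plasmid csrB may include effects of such a difference. All 6 glycogen genes rose (6 adjusted over the list alone, median 2.52, camera adjusted p = 6.33e-08). So did all 5 PGA genes (5 adjusted over the list alone, median 5.23, camera adjusted p = 5.03e-08) and 8 of 14 direct CsrA targets (8 adjusted over the list alone, with 1 lower, camera adjusted p = 0.000498). These 3 calls held with an estimated correlation, at adjusted p = 0.0281, 0.00191 and 0.0173.

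Other lists moved with plasmid csrB as well. All 15 TCA cycle genes rose (15 adjusted over the list alone, median 2.12, camera adjusted p = 8.23e-07, and adjusted p = 0.333 with an estimated correlation) and 30 of 31 RpoS list genes rose (31 adjusted over the list alone, median 2.21, camera adjusted p = 1.23e-20, and adjusted p = 0.0903 with an estimated correlation). Purine genes fell in 7 of 14 cases (7 adjusted over the list alone, median -0.68, camera adjusted p = 0.000317, and adjusted p = 0.336 with an estimated correlation), with purH 2.55-fold lower, against 14 of 14 in the csrA strain. The difference between these comparisons was not tested. Curli genes fell in 6 of 7 cases (6 adjusted over the list alone, median -1.43, camera adjusted p = 0.00281, and adjusted p = 0.246 with an estimated correlation). edgeR called 1670 genes, 917 higher and 753 lower, and 801 at least 2-fold.

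**Figure D4:**
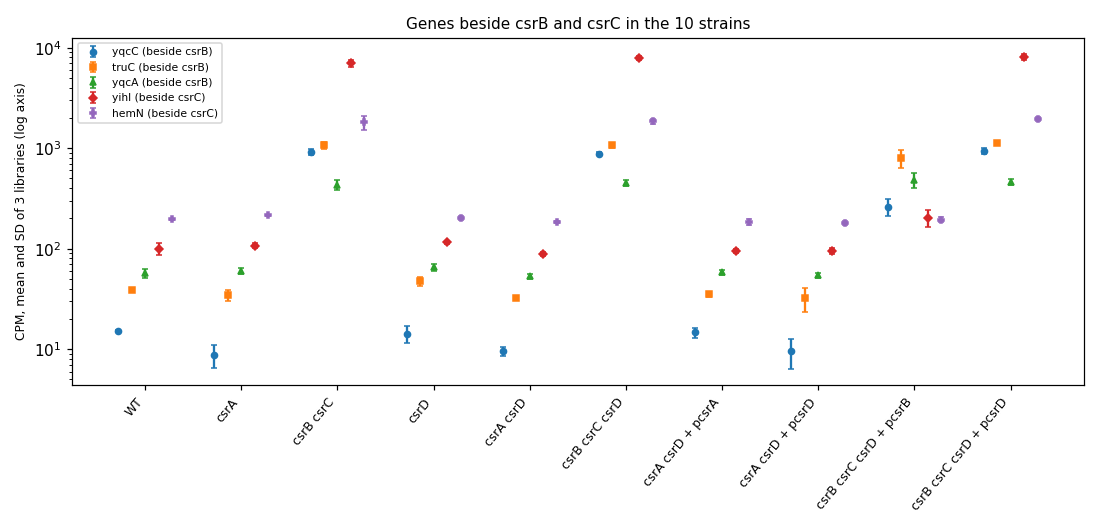
CPM (log axis, mean and SD of 3 libraries) of 3 genes beside csrB (yqcC, truC, yqcA) and 2 beside csrC (yihI, hemN) in the 10 strains. yihI stood at 100 CPM in wild type, 6993 CPM without csrB and csrC and 204 CPM in the strain with plasmid csrB.

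Plasmid csrD led to few calls beyond its own transcript. In the csrA csrD strain csrD rose to 1095 ± 88.0 CPM and csrB fell 4.65-fold, from 466 ± 83.4 to 100 ± 16.3 CPM (SD, n = 3; log2 -2.22, SE 0.18, edgeR adjusted p = 2.22e-08). csrC stood at 78.8 CPM in both strains. These were the 2 genes called by edgeR, with 41 at an unadjusted p under 0.05, and DESeq2 also called 2. In the csrB csrC csrD strain csrD was the only gene called by edgeR (log2 10.56, SE 0.36), with 112 at an unadjusted p under 0.05 and 1 called by DESeq2. Flagellar class 3 and chemotaxis genes had medians of 0.21 and -0.09, with 0 of 21 called in either strain (0 adjusted over the list alone, camera adjusted p = 0.00335 and 0.0104, and adjusted p = 0.772 and 0.994 with an estimated correlation). Their medians on csrD loss in these backgrounds were -1.28 and -1.10, so plasmid csrD gave back little or none of the fall. Why it did not was not tested. camera called 7 lists in each strain. With an estimated correlation 0 held in the csrA csrD strain and 1, the Csr circuit (adjusted p = 0.00821), in the csrB csrC csrD strain. The only member of that list called, over all genes or adjusted over the list alone, was csrD, the gene on the plasmid, so this call was fixed by the strain's construction. Wild type with plasmid csrD was not among the strains, so its effect could not be compared in a strain with csrA, csrB and csrC.

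Fold changes were then compared between contrasts that share no library. Across 4208 genes the change with plasmid csrA mirrored that without csrA (r = -0.869): 779 genes were higher without csrA and lower with plasmid csrA, against 241 for independent calls, and 586 the reverse, against 185. The change with plasmid csrB ran with that without csrA (r = 0.617), with 610 genes higher in both against 223 and 438 lower in both against 171. The csrB csrC and plasmid csrB contrasts were opposed (r = -0.474, and -0.311 without wild-type replicate C). The csrD contrast in wild type had r = 0.0332 with loss of csrD in the csrA background and 0.208 in the csrB csrC background, and 0.223 with plasmid csrB. Leaving out csrD replicate C or B moved the first between -0.116 and 0.104, so its sign was not settled. The last was 0.105 without csrD replicate C, 0.137 without wild-type replicate A and 0.416 without wild-type replicate C. Of the genes called in the csrD contrast, 15 were also higher and 64 also lower with plasmid csrB, against 3.46 and 13.9 for independent calls. Most of the 64 belonged to the flagellar lists, whose genes move together. They can therefore not be read as 64 separate agreements. The csrA and csrB csrC contrasts share the wild-type libraries, which gave a simulated covariance of 0.0513. The measured one was -0.0409 (r = -0.0698), and r was 0.14 without wild-type replicate C, against 0.514 in the simulation. With all libraries, 44 genes were higher in the first and lower in the second, against 15.4. These are correlations across genes, which are not independent replicates.

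**Figure D5:**
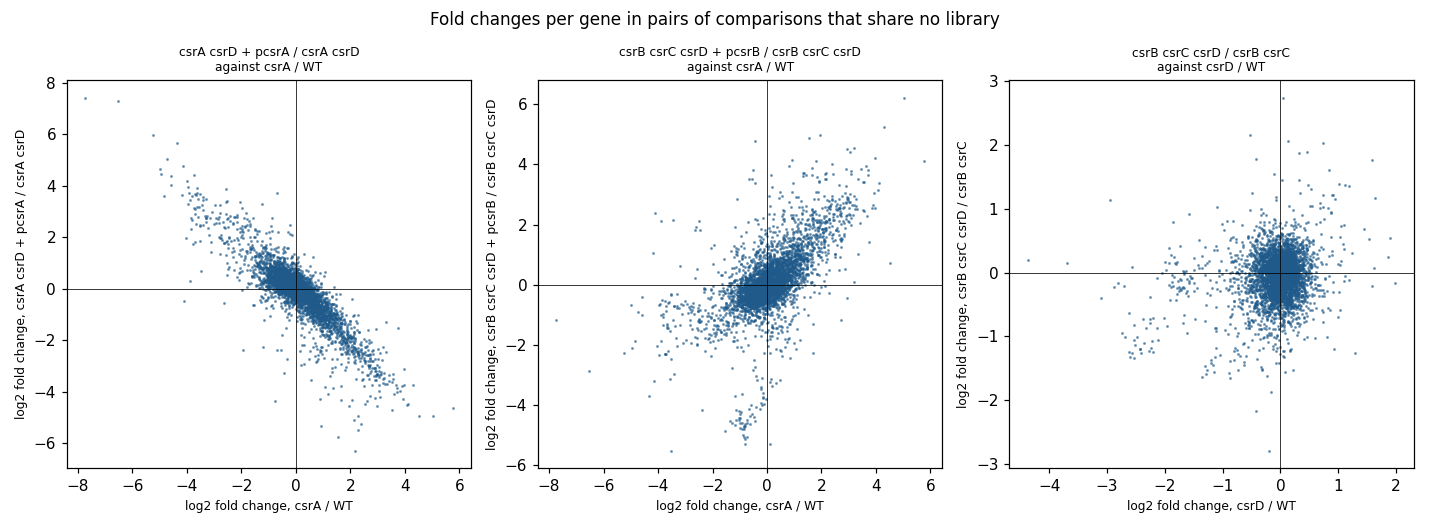
Log2 fold change of each gene in 3 pairs of comparisons that share no library, without csrA to csrD and pgaA to pgaD. The pair on the left had r = -0.869, the middle pair r = 0.617 and the pair on the right r = 0.208.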

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

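The interaction tests below were chosen before the data were examined, and no further test was chosen after their result was seen. They ask whether losing csrD moved a gene list by a different amount in a mutant background than in wild type. For each list the value is the median log2 fold change of the interaction, positive where the list fell less or rose more in the mutant background.

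Motility genes had positive interaction medians in both mutant backgrounds. In the csrA background the interaction medians were 1.53 for flagellar class 1 and 2 and 0.97 for class 3 and chemotaxis (camera adjusted p = 5.96e-35 and 6.58e-10, and adjusted p = 0.237 and 0.552 with an estimated correlation). In the csrB csrC background they were 1.5 and 1.24 (camera adjusted p = 6.55e-44 and 9.89e-19, and adjusted p = 0.0875 and 0.211 with an estimated correlation). Curli genes had interaction medians of 0.80 and 0.41 in these backgrounds (camera adjusted p = 0.00252 and 0.0323, and adjusted p = 0.36 and 0.413 with an estimated correlation). Class 1 and 2 genes averaged 5.51 to 5.98 log2 CPM in the csrA csrD strain and 5.61 to 6.05 in the csrA strain, and 4.24 to 5.70 in the csrD strain.

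In the csrA background 3 further lists had called interactions. The Fur iron acquisition median was 1.95, RpoS general stress -0.15 and colanic acid 0.28 (camera adjusted p = 5.9e-06, 0.0295 and 0.0304, and adjusted p = 0.988, 0.988 and 0.309 with an estimated correlation). The iron list averaged 4.27 log2 CPM in wild-type replicate C against 1.71 and 1.66 in replicates A and B, so a single culture moved the wild-type side of this interaction.

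In the csrB csrC background the metabolic and stress lists with called interactions below 0 were the TCA cycle at -0.84, RpoS general stress at -0.60, PGA polysaccharide at -0.58, glycogen metabolism at -0.56 and direct CsrA targets at -0.25 (camera adjusted p = 3.28e-06, 1.78e-14, 0.00136, 0.0103 and 0.0323, and adjusted p = 0.413, 0.236, 0.0875, 0.401 and 0.211 with an estimated correlation). Those above 0 were hydrogenases and acid-induced oxidases at 1.41, ribosomal RNA at 1.30, Fur iron acquisition at 1.21, purine biosynthesis at 0.38 and ribosomal proteins at 0.23 (camera adjusted p = 0.00824, 7.33e-05, 0.0012, 7.33e-05 and 1.28e-07, and adjusted p = 0.62, 0.401, 0.741, 0.401 and 0.612 with an estimated correlation). Single wild-type cultures stood apart for some of these lists, among them the hydrogenases at 6.12 log2 CPM in replicate A against 3.99 and 3.56, the TCA cycle at 8.77 in replicate C against 7.49 and 7.08, and the iron list in replicate C as given above. The ribosomal RNA list averaged 2.62, 2.58 and 0.64 log2 CPM in replicates A, B and C of the csrB csrC csrD strain, so its value rested on 2 cultures. Ribosomal RNA had been depleted and made up 0.00871, 0.00867 and 0.00278% of counts in these libraries. The list therefore holds reads left after depletion and cannot be read as the ribosomal RNA level of the cells. None of the 19 interaction list calls held with an estimated correlation, and edgeR called 0 genes in either interaction, with 399 and 298 at an unadjusted p under 0.05 and 17 and 6 called by DESeq2 in the csrA and csrB csrC backgrounds.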

How the results depend on the processing

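The alternative without the genes beside csrB and csrC was chosen after seeing the data. Where a value below differs, the cause was not tested unless stated. With only the libraries of the contrast in the fit, edgeR called 31 genes for csrB csrC, 27 for csrD, 12 for csrD loss in the csrA background and 45 in the csrB csrC background. DESeq2 called 208, 117, 20 and 80, and 17 and 6 for the interactions in the csrA and csrB csrC backgrounds. Without non-coding and engineered genes 0 were called for csrD loss in the csrA background and for plasmid csrD in both strains, as the called genes were themselves left out. Named genes kept direction and side of the threshold in 7362 tests under the alternatives other than leaving out a single library, against 93 weaker and 74 stronger.

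Leaving out each library in turn gave 49 calls (without csrB csrC replicate B) to 98 (without wild-type replicate A) for csrB csrC, 2 to 16 (without csrA replicate B) for csrD loss in the csrA background, and 7 (without csrB csrC csrD replicate A) to 22 (without csrB csrC replicate A) in the csrB csrC background. The csrA interaction had 0 or 1 (without wild-type replicate B). tnaB, a tryptophan carrier gene, ran from log2 -1.75 without wild-type replicate C to 1.75 without replicate A in the csrA strain. fhuF, an iron gene, ran from -5.22 without wild-type replicate B to 0.0113 without replicate C in the csrB csrC strain. The correlation of the plasmid csrA and plasmid csrD contrasts ran from -0.174 without plasmid csrD replicate A to 0.0183 without csrA csrD replicate A.

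With the replicate letter as a block (replicate block) the counts were 2051 for csrA, 109 for csrB csrC, 95 for csrD, 1827 for plasmid csrA and 1745 for plasmid csrB. Among 135 pairs of libraries with the same letter the mean residual r was 0.0582, against -0.0297 among 270 pairs with other letters, and 16 of 30 libraries were closest to a library of their own letter. Without the 4 genes on each side of csrB and csrC, 99 genes were called for csrB csrC and 1661 for plasmid csrB. Estimated correlations left 214 of 319 list tests as they were and weakened 105.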

Other observations

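The tests of explanations in this part, but not the regroupings of libraries in its last paragraph, were chosen after the result was seen, and the fim and prophage genes and those beside csrB and csrC were singled out after their values were seen. btsT, a high-affinity pyruvate transporter gene, fell 18.1-fold in the csrA strain, from 2097 ± 960 to 116 ± 48.6 CPM (SD, n = 3; log2 -4.18, SE 0.48, edgeR adjusted p = 1.98e-07), and rose 12.5-fold with plasmid csrA. cstA, a carrier induced by carbon starvation and a textbook CsrA target, rose 5.63-fold in the csrA strain, fell 6.49-fold with plasmid csrA and rose 2.05-fold with plasmid csrB. uhpT, the hexose phosphate carrier gene, fell 5.78-fold without csrD and 16-fold with plasmid csrB, to 1.75 ± 0.164 CPM. It stood 2.57-fold higher without csrB and csrC, a call lost without any library of these strains but wild-type replicate B (log2 1.44 or less).

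Sulfur assimilation and envelope stress genes moved with plasmid csrB. Of 12 sulfur genes 10 fell (11 adjusted over the list alone, median log2 -2.0, camera adjusted p = 0.000366, and adjusted p = 0.422 with an estimated correlation), with cysP, the sulfate-binding protein gene, 5.40-fold lower. Replicate A of that strain averaged 8.14 log2 CPM over this list, close to the 8.08 of replicate A without the plasmid, against 5.04 and 6.66 in its replicates B and C. SigmaE envelope stress genes rose in 9 of 15 cases (14 adjusted over the list alone, median 0.50, camera adjusted p = 0.000667, and adjusted p = 0.333 with an estimated correlation). The csrA csrD strain with plasmid csrA, compared with wild type after the data were seen, had 69 genes called by edgeR, 33 higher and 36 lower, against 1995 for the csrA strain.

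Of 16 genes beside csrB and csrC 7 were called higher without csrB and csrC, while yihA beside csrC was called lower (log2 -0.50). A change of CsrA activity would move them with plasmid csrA too. The median of the 6 called at least 2-fold higher was 0.11 there, which goes against it as the whole cause for these 6. With plasmid csrA, however, csrB stood at 96072 CPM, so CsrA activity there need not match that without csrB and csrC. polA, called higher by less than 2-fold (log2 0.43), was also called higher with plasmid csrA (0.54) and lower with plasmid csrB (-0.47). Of the 6, yqcC was called in the predicted direction with plasmid csrA (log2 0.63) and without csrA (-0.81). gudP, another of the 6, was called in the other direction without csrA (log2 0.82), at 0.971 CPM in wild type and 1.71 CPM without csrA. Their position at the altered sites stays open, since the count of 7 of 16 genes called higher there against 33 of 4198 others (one-sided Fisher exact p = 4.3e-11) restates the pattern. A level set by CsrB equally at both sites is opposed by plasmid csrB, where the median change at the csrB site exceeded that at the csrC site by 3.96 (-0.30 against -4.26), although yqcC and truC at the csrB site were also called lower (log2 -1.76 and -0.42). In that strain csrC counts were 2.75 CPM against 98.8 CPM without the plasmid, so its csrC site may differ from that of its empty-vector parent, which remains open.

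The 7 fim genes, for type 1 fimbriae, fell without csrD in wild type and in the csrB csrC strain, with medians of -1.16 and -1.39. If absence of the csrD transcript alone caused this, plasmid csrD would restore them, but it gave back 21.6% of the fall in the csrB csrC background, with 0 of 7 fim genes called by edgeR (112 of all genes had an unadjusted p under 0.05, and DESeq2 called 1). A plasmid csrD without activity is opposed by csrB, which changed by log2 -2.22 with it in the csrA csrD strain, although that is another background. Another heritable difference of the strains without csrD could leave the genes low, as their median was still -1.05 with plasmid csrD against the csrB csrC strain and -1.96 with plasmid csrA in the csrA csrD strain against wild type, with 7 of 7 called. Against it, plasmid csrB gave a median of 0.82 in a strain without csrD (7 of 7 positive, 4 called), csrA loss with csrD present gave -1.12 and csrD loss without csrA -0.43 (7 of 7 negative, 0 called by edgeR), so this stays open.

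In the 12 libraries of strains without csrB and csrC, 8 neighbouring prophage genes between ybcL and nmpC had 1 count in all, against 4078 in the other 18 libraries. Regulation by CsrB through CsrA is opposed by plasmid csrB, with which 0.141% of the level in the other strains was present. A missing chromosome segment in that strain line stays open, since the highest count of any of the genes in any of its strains, 1, restates the pattern. The bordering gene ybcL had 21 counts against 707, while ybcK and nmpC further out stood at ratios of 0.888 and 0.516 to the other strains, and whether DNA is missing may be settled by sequencing it. If it is missing, effects assigned to csrB and csrC may include those of this segment.

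Regrouping the libraries of a pair of strains gave only 10 splits each, too few for a share under 0.05. The real grouping alone, 1 of 10 splits, reached its count of calls for csrA (1995, highest other 0), csrB csrC (107, highest other 42), csrD (97, highest other 0), csrD loss in the csrA (2, highest other 0) and csrB csrC background (18, highest other 0), plasmid csrA (1803, highest other 0) and plasmid csrB (1670, highest other 0). By genes at an unadjusted p under 0.05, another split exceeded the real one for csrD (610 against 333), csrD loss in the csrA background (722 against 434) and plasmid csrD in the csrA csrD strain (328 against 41) and the csrB csrC csrD strain (471 against 112). For plasmid csrD 3 of 10 splits reached the 2 calls in the csrA csrD strain, with 13 the highest other, and 2 of 10 reached the 1 call in the csrB csrC csrD strain, with 3 the highest other. For the interactions the real count was 0, which any split reaches (100 of 100), so the comparison says nothing about chance. Other splits called up to 80 and 125 genes there. By genes at an unadjusted p under 0.05, another split exceeded the real one in the csrA (808 against 399) and the csrB csrC background (645 against 298). For the pairs of strains, counts above the real one point to some structure of the samples, and what it was has not been tested. The interaction splits could exchange csrD and wild-type libraries in part or in full. The effect of losing csrD in wild type is then added where the real contrast subtracts it. Higher counts in those splits can therefore hold that effect, and nothing about other structure is concluded from them.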
